A study of Arabidopsis thaliana with 8 samples.

How the data were processed

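Transcript levels were measured on 8 ATH1 arrays, single-colour oligonucleotide arrays of Arabidopsis thaliana, with 1 array per sample of whole Col-0 seedlings. Per the labels' protocols, the seedlings grew on agar under long days and were harvested 6 days after germination, which was 8 days after sowing. The labels put 4 arrays in a wildtype group and 4 in a group called E2Fa-Dpa. No label says whether samples of a group were grown separately, so p-values measure the spread between these samples, part of which may be technical. The arrays fall into 4 close pairs, each of 1 group and 1 array set. The closest, E2Fa-Dpa replicates 1 and 4, correlate at 0.9941 and the least close, wildtype replicates 3 and 4, at 0.9743. If the 2 arrays of a pair came from 1 RNA, n would be 2 per group where 4 is given, and 1 per group within an array set.

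The deposited values are intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes name MAS5 as the method, without a version. The authors' scaling left a trimmed mean intensity of 100 on each array. Detection calls and the scaling target were not given in the sources used here. The arrays hold 22810 probe sets, of which 64 are manufacturer's controls. The other 22746 were tested, with no filter on low signal. The number of arrays limits the precision. The median signal per array ranged from 37.88 to 44.4, and 30.3% to 35.7% of probe sets lay under a signal of 16.

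Signals were used as log2(signal + 16), so fold changes understate the change of dim probe sets. The contrast E2Fa-Dpa minus wildtype was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, all 8 arrays, no covariate). P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets with a threshold of 0.05. All adjusted p-values given for single genes or probe sets come from that model unless another is named. The procedure was tested on simulated data for this comparison with 22746 probe sets. It recovered 78 of 100 probe sets changed 2-fold and 94 of 100 changed 4-fold, with 10 false calls.

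Gene names came from the platform annotation that pairs probe sets with genes. Of the tested probe sets, 13513 name 1 gene, 503 name several and 8730 are not listed and stay unnamed. Through gene numbers, 13436 of the 13513 matched the RefSeq gene table of assembly TAIR10.1, which was used for names and loci only. The other 77 kept the annotation's name. No probe set is named here from a probe set with several genes, and families sharing a probe set are described as families. The annotation as used here pairs no probe set with E2FA or DPA, so the planned check of both genes' levels was not made. The planned motif test in promoters needs a genome sequence and was not run.

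Before the data were examined, 19 gene lists with 370 genes were written, and 56 of these genes had a named probe set. The lists of the transgenes, of nucleotide synthesis, of nitrogen metabolism and of seed storage had no measured member. Each gene was represented by its probe set with the highest mean over all 8 arrays, among 13355 genes. The 4 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over these lists. In simulated data on 13355 genes, 50 of 50 lists of 7 genes shifted 2-fold were called, and 0 of 50 unshifted lists. Correlations estimated from the real data lay above the preset 0.01. They were 0.184 for replication, 0.674 for histone, 0.364 for photosynthesis and 0.215 for cell wall. Because few listed genes had named probe sets, 15 more lists were written after the annotation was read but before any group value was seen. Sets of the plastid-encoded and mitochondrion-encoded genes joined them, and these 17 sets were adjusted among themselves. They are called added lists. The results of 1 of them are not reported here, and the adjustment still counts it. From the one on flavonoids, 1 gene was taken out after group values had been seen, because its symbol belongs to a chitinase.

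Named genes follow a rule set before the data were examined. Among probe sets past the threshold that name 1 gene and whose groups do not overlap, the 15 with the largest rise and the 10 with the largest fall were taken, then the 3 measured members with the smallest p of each list. The same rule of 3 was applied to the added lists. Other genes named below were chosen after their values were seen.

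The labels give no batch. The Bacillus poly-A controls, RNAs that can be added to a sample before labelling, gave signal on 4 arrays and almost none on the other 4. This split, read from control probe sets alone after the data were seen, was treated as a technical batch, with 2 arrays of each group on either side. Results are given with it as a block and within each set of 4 arrays. The replicate numbers are shared between the groups but do not mark shared samples, and a fit with them as a block was an alternative. Other alternatives were pseudocounts of 1 and 64, quantile, cyclic loess and median scaling, leaving out the dimmest 40% of probe sets, other variance models, array weights, leaving out each array, an estimated correlation in camera and the mean of a gene's probe sets. Averages of the 4 pairs of arrays of one group and batch, and these pairs as a random block, were added after the data were seen.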

Results

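The series compared whole seedlings labelled E2Fa-Dpa with wildtype seedlings of the Col-0 accession, 4 arrays each, and its title names the target genes of E2F as the subject. E2Fa and DPa are transcription factors that bind promoters as a dimer, and E2F sites are known from genes of the S phase of the cell cycle. The labels do not say how the E2Fa-Dpa seedlings were made. MAS5 signals, linear intensities of each probe set scaled by the authors, were compared between the groups.

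All 7 measured genes of a DNA replication list rose in the E2Fa-Dpa seedlings, and 4 of 7 of a histone list, while none of the 4 measured genes of mitosis passed the test. As written, these lists held 52, 30 and 30 genes, so most members were not measured. In an added list of 23 division genes 1 rose, and 5 with the array set as a block. The replication list kept its call with an estimated correlation between genes (adjusted p = 0.0108), and the histone list lost it (adjusted p = 0.094). PRL, the MCM7 subunit of the replicative helicase, went from a signal of 94.6 ± 17.4 in wildtype to 576.3 ± 108 in E2Fa-Dpa (SD, n = 4 each). Of 10 measured genes induced by cold or dehydration 3 fell, among them COR47 from 1601 ± 492 to 477.9 ± 92.8. Cell wall loosening genes were lower for 12 of 12 measured members, 1 of them past the threshold, and plastid-encoded transcripts for 65 of 69 genes, 5 of them past it. These 3 lists had calls that were lost when camera estimated the correlation (adjusted p = 0.111, 0.094 and 0.146). For the cold and dehydration list that estimate, 0.00191, lay under the preset 0.01. In all, 992 probe sets rose and 669 fell by limma with Benjamini-Hochberg adjustment, 405 and 198 of them at least 2-fold. The total of 1661 fell to 674 without E2Fa-Dpa replicate 4, 717 without E2Fa-Dpa replicate 1, 940 without E2Fa-Dpa replicate 3, 946 without wildtype replicate 1 and 985 without wildtype replicate 2. With the 4 close pairs of arrays as a random block it fell to 454, and with each pair averaged to 2. At 1 probe set per gene, 488 genes rose and 343 fell. All 4 values of a group lay above the 4 of the other in 9.53% of probe sets for a rise and 6.77% for a fall, against 2.86% by chance for both directions together. With each array centred on its median instead of the authors' trimmed mean, 781 rose and 1080 fell, and with cyclic loess 854 rose and 851 fell.

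The arrays also differed in a way the groups do not explain. The poly-A control RNA dap gave signals of 79.4 to 121 on wildtype replicates 3 and 4 and E2Fa-Dpa replicates 1 and 4, and of 0.644 to 6.17 on the other 4 arrays. Between these array sets, 5976 probe sets differed in a fit with the group in the model. With the array set as a block, 2653 probe sets rose and 2223 fell in E2Fa-Dpa, and all 1661 changed probe sets of the fit without it were among them. Within the 4 arrays without control RNA 1253 rose and 1170 fell and within the 4 with it 853 rose and 671 fell. Each fit within a set compares 1 close pair of arrays with another, so its p-values measure the spread within pairs. The fit with the block also rests mostly on that spread. If a pair came from 1 RNA, these calls would not measure the spread between samples. The block leaves fold changes as they are, because each set holds 2 arrays of each group.

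**Figure D1:**
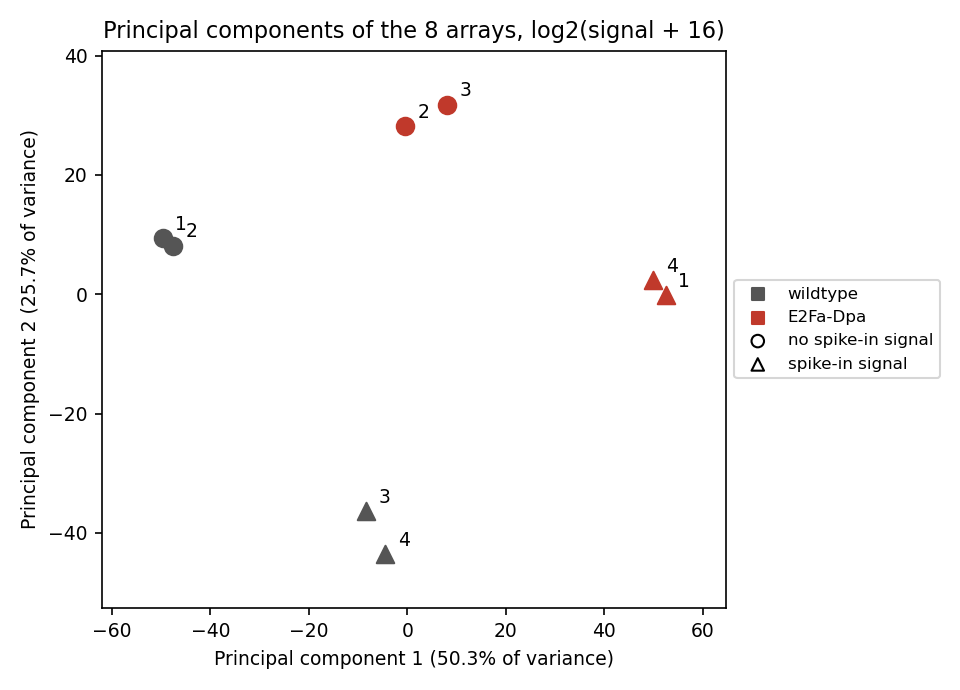
Principal components of log2(signal + 16) over the 22746 tested probe sets, 1 point per array, with the replicate number beside it, the group as colour and signal of the poly-A control RNAs as shape. Component 1 holds 50.3% and component 2 25.7% of the variance, and the arrays fall into 4 pairs, each of 1 group and 1 array set.

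The probe sets with the largest rises were 263955_at and 251052_at, which are not listed in the annotation used here. The first went from 27.52 ± 6.19 to 3394 ± 234, a log2 fold change of 6.30 ± 0.131 (SE, adjusted p = 3.14e-08). The second went from 49.87 ± 8.59 to 3282 ± 409, a log2 fold change of 5.65 (adjusted p = 6.35e-08). Among named genes AT1G18130 rose from 8.099 ± 1.57 to 676 ± 389 (log2 fold change 4.65, adjusted p = 0.000205). Its rise was 3.81 on the log2 scale in the arrays without control RNA and 5.50 in those with it, a difference past the threshold (adjusted p = 0.0263 for the interaction). AT4G28310 followed with 4.12 and AT1G68240 with 3.28 on the log2 scale.

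Several of the 15 largest named rises are known by function. FBL17, an F-box protein that promotes the removal of inhibitors of cyclin-dependent kinases, rose from 94.42 ± 13.1 to 595.2 ± 120. The chromatin remodelling gene chr31 rose from 3.182 ± 2.37 to 98.42 ± 9.77, and ICL, the isocitrate lyase of the glyoxylate cycle, from 14.2 ± 19.6 to 164 ± 67.7. Their log2 fold changes were 2.46, 2.58 and 2.69. The remaining named rises were AT3G58540, AT5G05180, AT5G54970, AT3G02670, AT4G27510, AT1G33420, AT4G13690, AT3G02820 and PRL, between 2.42 and 3.07 on the log2 scale. The 15 genes kept their calls when any single array was left out.

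All 7 measured genes of the replication list rose, over all probe sets and also adjusted over the list alone, with a median log2 fold change of 1.51 (camera, adjusted p = 2.13e-11). The call held with an estimated correlation (adjusted p = 0.0108). ICU2, the catalytic subunit of DNA polymerase alpha, rose by 1.82 ± 0.139 and POLD3, a subunit of DNA polymerase delta, by 1.55 ± 0.133 on the log2 scale (SE). POLA3, the small primase subunit, and PSF2, part of the GINS complex of the replication fork, rose by 1.51 and 1.36, and PSF2 lost its call without E2Fa-Dpa replicate 1 or 4 (highest adjusted p 0.0546). The list's median was 1.28 in the arrays without control RNA and 1.74 in those with it, and the adjusted p was 9.62e-10 with the array set as a block. The added list of replication and repair genes, which shares 10 of its 35 genes with earlier lists, had 23 risen members and none fallen, and 26 risen with the array set as a block. Its median was 0.96 (camera, adjusted p = 2.03e-25, and 0.00724 with an estimated correlation), with 0.83 and 1.04 within the array sets. UNG, which removes uracil from DNA, rose from 14.82 ± 6.21 to 131.1 ± 24.7.

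The 7 measured members of the histone list all encode H2B. Of these, 4 rose over all probe sets, 7 adjusted over the list alone and 7 with the array set as a block, with a median log2 fold change of 1.21 (camera, adjusted p = 6.9e-07). The list's call was lost with an estimated correlation (adjusted p = 0.094). HTB2 rose from 140 ± 45 to 571 ± 286, AT2G37470 (HTB5) by 1.21 and AT3G53650 (HTB6) by 1.87 on the log2 scale. The median was 0.89 within the arrays without control RNA and 1.61 within those with it. Probe sets that the annotation pairs with whole histone families moved likewise. All 5 probe sets of the H3.1 family and 4 of 5 of the H4 family rose, and 10 of 10 with the block, with log2 fold changes of 1.26 to 2.50. Of these 9 calls 4 held whichever array was left out, and the other 5 were lost without wildtype replicate 1 or 2 or E2Fa-Dpa replicate 1 or 4, 1 of them also without wildtype replicate 3 or E2Fa-Dpa replicate 3 (highest adjusted p 0.103). The annotation used here pairs each of these probe sets with all genes of its family, so their rises are not assigned to single genes. Both measured genes of the chromatin list, the histone chaperones SGA2 (ASF1A) and ASF1B, rose by 0.88 and 1.47. HTB2, AT2G37470 and ASF1B lost their calls without E2Fa-Dpa replicate 4, HTB2 also without wildtype replicate 1 or 2 and AT2G37470 without E2Fa-Dpa replicate 1 (highest adjusted p 0.0558 over single arrays left out).

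**Figure D2:**
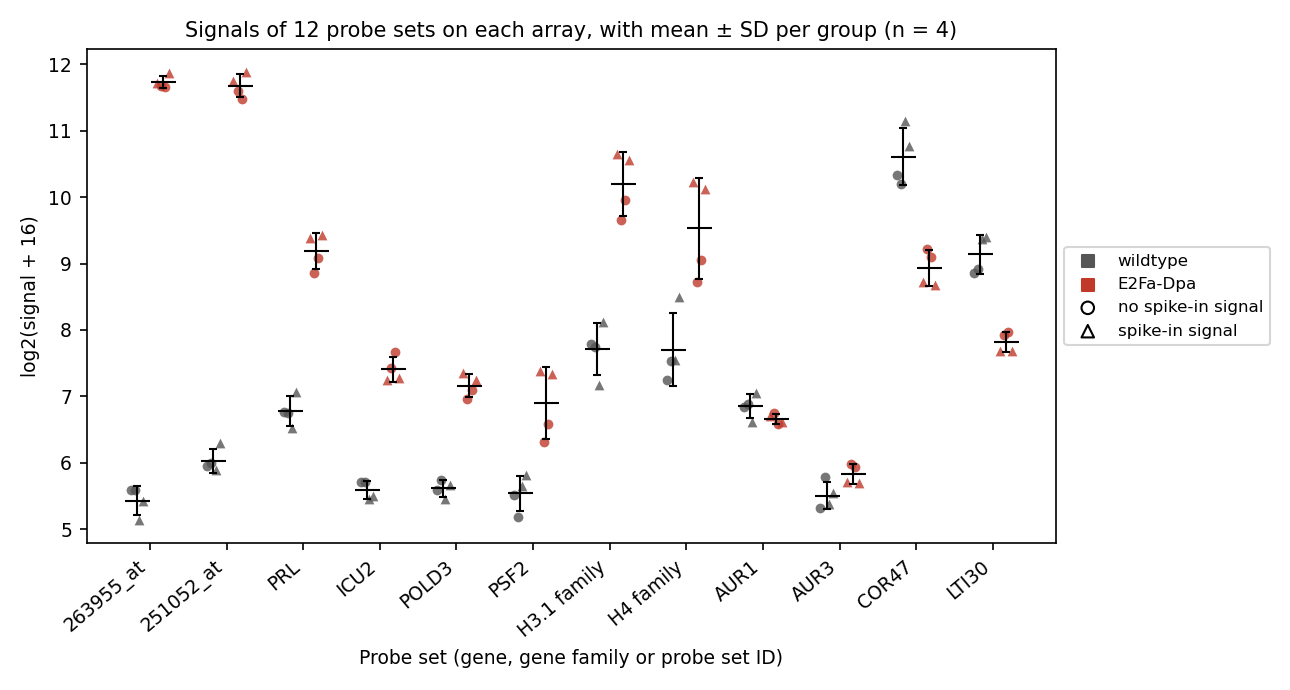
Signals as log2(signal + 16) of 12 probe sets on each of the 8 arrays, with bars for the mean and SD per group (n = 4), the group as colour and the array set as shape. The E2Fa-Dpa points of PRL, ICU2, POLD3, PSF2 and of the H3.1 and H4 family probe sets lie above all wildtype points, those of COR47 and LTI30 lie below, and AUR1 and AUR3 did not pass the test.

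None of the 4 measured mitosis genes passed the test, over all probe sets or adjusted over the list alone. The Aurora kinases AUR1, AUR2 and AUR3 had log2 fold changes of -0.19, -0.35 and 0.32 (adjusted p = 0.424, 0.35 and 0.229). In an added list of 23 division genes only Haspin, a histone H3 kinase, rose, by 0.79 (adjusted p = 0.026), and 5 rose with the array set as a block. The list's median was 0.13 (camera, adjusted p = 0.411), with 0.20 and -0.02 within the array sets. ATSMC2, a condensin subunit, had 0.79 (adjusted p = 0.0593) and WYR 0.41 (adjusted p = 0.11), and both passed with the block (0.00249 and 0.0462). SIM and AT1G08180 (SMR2), written in a list headed G1 regulators, had 0.11 and -0.13, and the repair polymerase AT4G32700 (TEB) -0.09, none past the threshold. Haspin lost its call without wildtype replicate 2, 3 or 4 or E2Fa-Dpa replicate 1 or 4 (highest adjusted p 0.0878).

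Among the fallen genes, COR47 and COR15A, both induced by cold and dehydration, were the measured members of the stress list and both fell. COR15A fell from 459.4 ± 540 to 33.14 ± 10.6, and COR47 had a log2 fold change of -1.68 (adjusted p = 0.00279). In the added dehydration list 3 of 10 genes fell, the third being the dehydrin LTI30, from 556.1 ± 114 to 210.6 ± 23.7. The list's median was -0.44 (camera, adjusted p = 0.00163, and 0.111 with an estimated correlation), with -0.47 and -0.98 within the array sets. The estimated correlation of this list was 0.00191, under the preset 0.01. A higher correlation between its genes is thus not why the call was lost. COR15A kept its call in 2 of 8 fits with an array left out, while COR47 and LTI30 kept it in all 8.

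The other large falls were ATSPS4F, a sucrose phosphate synthase, from 129 ± 52.5 to 23.1 ± 18.3, AT4G12830, AT3G19680, AT1G66100, AT5G01015, psbB, AT4G16260, AT3G57020 and AT4G33666, between -1.91 and -1.71 on the log2 scale. Of the 10 largest named falls 3 kept their calls whichever array was left out, AT4G12830, AT3G19680 and AT5G01015. The other 7 lost theirs without at least E2Fa-Dpa replicate 4 (highest adjusted p 0.116, for AT4G16260). Of unnamed probe sets, 255549_at fell most, with -2.40, then 249037_at with -2.37.

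Expansins and xyloglucan hydrolases, enzymes and proteins that loosen the cell wall, were lower for 12 of 12 measured members of the cell wall list. The expansin EXPB3 fell from 285.9 ± 79.6 to 99.46 ± 38.3, the only call over all probe sets and adjusted over the list alone, and 5 fell with the array set as a block. XTH19 and XTH32 had -0.51 and -1.52 on the log2 scale (adjusted p = 0.0935 and 0.125, and 0.0405 and 0.00927 with the block). The list's median was -0.41 (camera, adjusted p = 0.000177, and adjusted p = 0.094 with an estimated correlation), with -0.62 and -0.48 within the array sets. In the added list of wall gene families, which shares 14 of its 42 genes with earlier lists, 6 fell and none rose, among them EXLA1 with -1.66 and the glucanases GH9B8 and GH9B13 with -1.20 and -0.94, and 12 fell and 1 rose with the block. Its adjusted p was 6.22e-05 by camera and 0.409 with an estimated correlation. EXPB3 lost its call without E2Fa-Dpa replicate 1 or 4 (highest adjusted p 0.0558).

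None of the 7 measured photosynthesis genes passed the test for single genes, with PSAN, LHCB4.1 and PSBY at -0.34, -0.37 and -0.41 on the log2 scale. With the array set as a block PSAN and PSBY fell (adjusted p = 0.0236 and 0.0226). As a list they were lower, with a median of -0.32 (camera, adjusted p = 0.0256), but not with an estimated correlation (adjusted p = 0.245), nor with quantile scaling (0.243) or cyclic loess (0.203). Within the arrays without control RNA the median was -0.36 and within those with it -0.27. In the added list of nuclear photosynthesis genes, which holds these 7 among its 21, NdhL, PRK and PSB27 fell, by camera with an adjusted p of 0.00028 (0.25 with an estimated correlation), and 9 fell and 1 rose with the block. PRK, the phosphoribulokinase of the Calvin cycle, went from 2665 ± 351 to 1566 ± 344. NdhL kept its call whichever array was left out, while PRK and PSB27 lost theirs without wildtype replicate 1 or 2 or E2Fa-Dpa replicate 1, 3 or 4 (highest adjusted p 0.109). Of 69 plastid-encoded genes 5 fell and none rose, and 22 fell with the array set as a block. psbB and psbT, of photosystem II, had log2 fold changes of -1.75 and -1.44, and ndhH -0.65. The call of psbB was lost without wildtype replicate 2, 3 or 4 or E2Fa-Dpa replicate 1, 3 or 4 (highest adjusted p 0.0902), that of psbT without wildtype replicate 2 or E2Fa-Dpa replicate 3 (0.0527) and that of ndhH without wildtype replicate 2 or E2Fa-Dpa replicate 1 or 4 (0.0652). The median was -0.35 (camera, adjusted p = 7.49e-08, and 0.146 with an estimated correlation), with -0.38 and -0.32 within the array sets.

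**Figure D3:**
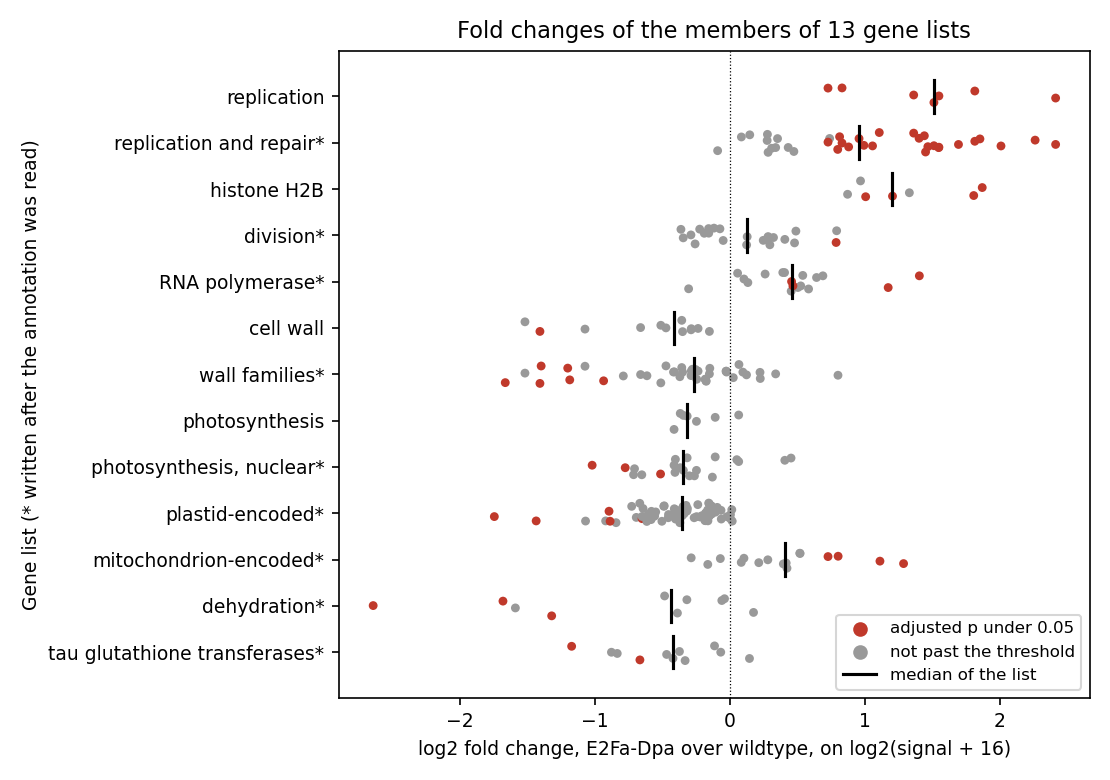
Log2 fold changes of E2Fa-Dpa over wildtype for the members of 13 gene lists, 1 point per gene, red where the adjusted p was under 0.05, with a bar at each list's median. All 7 replication genes lie to the right of 0 and all 12 cell wall genes to the left, and the median of the division list is 0.13.

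Of 3 measured auxin-responsive genes, IAA29 rose from 35.08 ± 10.4 to 121.5 ± 18 and WES1 (GH3.5), which conjugates auxin to amino acids, by 1.18 on the log2 scale, while GH3.3 had 0.59 (adjusted p = 0.287). The cytokinin response regulators ARR15 and RR16 had -0.45 and -0.25, not past the threshold. WES1 lost its call without E2Fa-Dpa replicate 1, 3 or 4 (highest adjusted p 0.0609).

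In the lists of cell type and organ markers written before the data were examined, few genes were measured and none passed the test over all probe sets. Of 8 other root-expressed genes, chosen later to compare the array sets, 8 lay lower in E2Fa-Dpa and 2 passed, AT5G17820 and PYK10, each of which kept its call in 2 of 8 fits with an array left out, and 5 passed with the array set as a block. The root hair expansins EXPA18 and EXPA7 had -0.37 and -0.26, the meristem gene CLV3 0.12 and the trichome regulator TRY -0.27. The stomatal genes SPCH, FMA (FAMA) and MUTE had 0.51, 0.18 and 0.13, and SPCH (adjusted p = 0.104) rose adjusted over the list alone and with the array set as a block (0.0383). The ratio of 3' to 5' signal of the actin control was 1.62 ± 0.309 in wildtype and 1.54 ± 0.368 in E2Fa-Dpa, and that of the ubiquitin control 1.48 ± 0.276 and 1.52 ± 0.398. That of the GAPDH control was 0.87 ± 0.0364 and 0.967 ± 0.047, with all E2Fa-Dpa values, 0.931 to 1.03, above all wildtype values, 0.835 to 0.918.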

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

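In this part, the test of 3' bias, the test of scaling and the count of splits that keep pairs of arrays whole were chosen after the result was seen, and the array sets themselves were read from the data.

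The control probe sets for Bacillus poly-A RNAs were not among the tested probe sets and served only to define the array sets. They gave signal on 4 arrays above that on the other 4, by 1.33 on the log2(signal + 16) scale. The split crosses the groups, with wildtype replicates 3 and 4 and E2Fa-Dpa replicates 1 and 4 on one side, and 5976 probe sets of plant genes differed along it. A bias toward 3' ends of the labelled RNA is argued against as the whole cause, because the ubiquitin 3' to 5' ratio was lower in the arrays with control RNA, by -0.572 (1.21 ± 0.058 against 1.78 ± 0.118, SD, n = 4 each), and the actin ratio higher. Another harvest time of day stays open, since the clock-controlled genes GI and AT4G33980 were higher in the arrays with control RNA by 1.15 and 2.74, each over the bound set before their values were seen. The direction of that bound was taken from COR27, already seen higher in those arrays (by 2.998), and AT4G33980 is also named COR28. The bound was thus not set blind to this pattern. More root tissue in the arrays without control RNA also stays open, because the median difference of 8 root-expressed genes, -0.48, lay between both bounds, with 5 lower and 1 higher past the threshold. No biological explanation from the groups was tested, since each set holds both groups equally.

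Risen probe sets outnumbered fallen ones, at 59.7% of those changed. The share was 50.1% with cyclic loess (95% binomial interval 47.7% to 52.5%) and 52.6% with quantile scaling (50.2% to 55%), both of which make the arrays alike. It was 42% with median centring, which moved the median fold change of all probe sets from 0.00403 to -0.0572 on the log2 scale, so that this share follows from the shift. The authors' trimmed mean scaling as the source of the excess and a real excess of rises in the E2Fa-Dpa group cannot be told apart, since the interval lies above 50% with quantile scaling and spans it with cyclic loess. Both intervals take probe sets as independent, and genes that move together may make them too narrow. Among probe sets changed at least 2-fold the share was 67.2%, with 63.1% under quantile scaling, 60.7% under cyclic loess and 56% under median centring. At this size rises thus outnumbered falls under each of these scalings. With array weights and the authors' scaling the share was 49.6%, where 603 rose and 612 fell.

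Over the 35 splits of the 8 arrays into 4 and 4, 2 gave at least as many changed probe sets as the groups, the real split with 1661 and the split along the array sets with 2345, so chance is not excluded by that count alone. No other split gave over 1. For changes of at least 2-fold only 1 of the 35 splits, the real one, reached 603, and the highest other, again along the array sets, gave 349. That share lies under 0.05, the smallest these splits can give, and counts against chance only if the 8 arrays are independent samples. They form 4 close pairs, and only 3 splits keep the pairs whole, too few for a share under 0.05, of which 1, the real one, reached 603 and the highest other gave 349. With the array set as a block, the real split gave 4876 changed probe sets, and the highest of the other 17 of the 18 splits that part each set evenly gave 0. Each of those 17 mixes the groups, so the group difference adds to its spread, and most also break close pairs. A count near 0 was thus likely from the start, and this count does not decide on chance.

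In 9 of 244 groups of 4 values tested for named probe sets, 1 array stood far from the other 3, where chance alone gives about 1 in 20. The gap as a share of the group's range was 0.969 for AT4G27510, 0.974 for FBL17, 0.938 for AT3G02820 and 0.903 for the H4 family probe set 251924_at in wildtype, each time at replicate 4. It was 0.924 for UGT74D1 and 0.847 for CYP71B23 in wildtype replicate 3, 0.878 for GH3.3 and 0.854 for CHLI2 in E2Fa-Dpa replicate 3, and 0.839 for NRPB9A in E2Fa-Dpa replicate 2. The signal of FBL17 was 74.81 in wildtype replicate 4 against 100.5 to 101.3 in the other wildtype arrays.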

How the results depend on the processing

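The array set block, the fits within array sets and the fits on pairs of arrays were chosen after the data were seen. The 4 tested lists kept their direction under each alternative run, and replication kept its call under all, with medians of 0.98 with a pseudocount of 64 to 1.74. Replication, histone and cell wall medians with an array left out ranged from 1.4 to 1.62, 1.08 to 1.37 and -0.52 to -0.34. The estimated correlation ended the calls of histone (median 1.21), cell wall (-0.41) and photosynthesis (-0.32). Photosynthesis also lost its call with quantile scaling (-0.115), cyclic loess (-0.15), median centring (-0.38), pairs averaged (-0.32), the arrays with control RNA alone (-0.27) and without wildtype replicate 1 or 3 or E2Fa-Dpa replicate 3 (-0.40 to -0.25 over single arrays left out). The changed probe sets numbered 5417 with array weights, which favoured E2Fa-Dpa replicates 1 and 4, and 4876 with the array set as a block. Leaving out an array gave 674 to 1696, with 946 without wildtype replicate 1, 985 without wildtype replicate 2, 717, 940 and 674 without E2Fa-Dpa replicates 1, 3 and 4. Changes of at least 2-fold numbered 965 with a pseudocount of 1, 236 with 64, since the pseudocount sets the fold of dim probe sets, and 1215 with array weights, and 424 to 733 with an array left out. Treating the 4 pairs of arrays as a random block left 454 and 373 at least 2-fold, and averaging them, 2 values against 2, left 2 and 2. Both count the array set within the spread, and the cause was not tested otherwise. With the replicate block the changed probe sets numbered 854 (549 up, 305 down), 822 of them shared with the fit without it. Deviations from the group mean of arrays with the same number correlated at -0.519 and -0.359 for numbers 1 and 3, whose arrays are in different array sets, and at 0.443 and 0.526 for numbers 2 and 4, which share one, against 0.308 to 0.553 for arrays of different groups and numbers that share one. The direction of the list test turned in lists without a call, where the median need not turn with it. Leaving out the dimmest 40% gave medians of -0.049 for division, -0.025 for tetrapyrrole and 0.069 for CYP71 genes, and array weights 0.056 for UGT genes. The tetrapyrrole list ranged from -0.099 to 0.054 with an array left out and had 0.048 in the arrays without control RNA, where CYP71 had -0.018. The tubulin median turned to -0.085 in the arrays with control RNA and -0.021 without wildtype replicate 1, and the direction of its test did not. The genes AT4G32700 and DFR, without a call, turned to 0.144 and 0.033 in the arrays with control RNA. The motif test and its alternatives and those for E2FA and DPA levels were not run. Signal near background limits dim genes, since 30.3% to 35.7% of probe sets lay under 16.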

Other observations

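Mitochondrion-encoded genes lay higher in E2Fa-Dpa for 13 of 16 measured genes, and 4 rose, cox2, ccb452, nad1 and nad9. The set holds only genes whose symbols start with nad, cox, ccb, matR or orfX. Many were dim, and with the dimmest 40% of probe sets left out 5 of those kept lay higher. Without the number kept, that count does not say whether the direction held among brighter genes. The respiratory subunit cox2 went from 10.37 ± 6.42 to 39.83 ± 2.57 (SD, n = 4), and ccb452 had a log2 fold change of 1.29. The median was 0.41 (camera, adjusted p = 0.000735, and 0.409 with an estimated correlation), with 0.14 in the arrays without control RNA, where the list lost its call (adjusted p = 0.143), and 0.59 in those with it (adjusted p = 9.44e-05). Of 18 genes in the added list of RNA polymerase subunits and ribosome assembly factors, 4 rose and 17 lay higher, with NRPB9A at 1.41, NRPB9B at 1.17 and IMP4 at 0.47 on the log2 scale. The list's adjusted p was 1.42e-05 by camera and 0.207 with an estimated correlation. Adjusted over the list alone 10 rose, and with the array set as a block 12, with medians of 0.38 and 0.49 within the array sets. With the block 6 mitochondrion-encoded genes rose. TUB1 and TUB7, of 7 tubulin genes, rose by 0.88 and 0.63 (list adjusted p = 0.112, and 0.0101 and 0.577 within the arrays without and with control RNA), and TUA1 had 0.59 (adjusted p = 0.102). Of the 8 fits with an array left out, nad9 and IMP4 kept their calls in 1, nad1 in 3, TUB7 in 5 and ccb452 in 6, and all of these but ccb452 lost them without wildtype replicate 1 or E2Fa-Dpa replicate 1 or 4, and ccb452 without E2Fa-Dpa replicate 3 or 4.

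Tau class glutathione transferases were lower for 10 of 11 genes, and GSTU27 and GSTU28 fell, GSTU27 from 262.1 ± 41.2 to 107.8 ± 21.2. The list's adjusted p was 0.00028 by camera and 0.146 with an estimated correlation. Adjusted over the list alone 5 fell, and with the array set as a block 6, with medians of -0.51 and -0.47 within the array sets. Among 15 SWEET sugar transporters SWEET1 rose from 75.06 ± 27.8 to 274.7 ± 28.1 and SWEET17 fell from 294.7 ± 124 to 89.51 ± 38.7, while SWEET16 had -0.54 (list adjusted p = 0.14). With the array set as a block, SWEET16 passed (adjusted p = 0.0367), 4 of the genes fell and the list was called lower (adjusted p = 0.0174, against 0.637 with an estimated correlation and no block). Of 47 UGT glycosyltransferases UGT71C5 rose by 1.22, and UGT74D1 and UGT71C1 had -0.79 and -0.66, both past the threshold (list adjusted p = 0.318), and 3 rose and 4 fell with the block. CHIL, of 8 flavonoid genes, fell from 116.5 ± 49.3 to 29.53 ± 9.26 (list adjusted p = 0.155, and 0.0221 and 0.432 within the arrays without and with control RNA), and ATG8B rose by 0.72 among 10 autophagy genes (list adjusted p = 0.161), of which 2 rose with the block. None of 19 CYP71 genes and 11 tetrapyrrole genes passed the test over all probe sets by limma (list adjusted p = 0.727 and 0.916), with CYP71B23 at 0.79 (adjusted p = 0.0608) and PORB at 0.53 (adjusted p = 0.149). With the array set as a block CYP71B23 and PORB passed (adjusted p = 0.00831 and 0.0308), and 3 CYP71 genes rose, 2 fell and 1 tetrapyrrole gene rose, with neither list called. UGT71C1 kept its call in 1 of 8 fits with an array left out, GSTU28 in 2, CHIL and ATG8B in 3 and SWEET17 in 4, and these 5 lost it without wildtype replicate 1 or 2 or E2Fa-Dpa replicate 1 or 4. Of 82 calls on named probe sets in all, 47 held in all 8 fits.

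The 8 root-expressed genes used above to compare the array sets, extensins, peroxidases and PYK10, all lay lower in E2Fa-Dpa, with a median of -0.63 on the log2 scale. AT5G17820 and PYK10 passed the test, with -0.80 and -0.59, and each kept its call in 2 of 8 fits with an array left out (highest adjusted p 0.105 and 0.11). With the array set as a block 5 of the 8 fell. Their lower level stands beside the falls in the cell wall lists, and root share was not measured apart from such transcripts.

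The tests in this paragraph were chosen after the results were seen. Of 35 replication and repair genes 23 rose, and 26 with the array set as a block, against 1 and 5 of 23 division genes. For the genes of these lists, a rise of all cell cycle genes alike is argued against by the difference of both list means per array, which was 0.91 higher on the log2 scale in E2Fa-Dpa (exact permutation test over arrays, two-sided, p = 0.0286, adjusted p = 0.0286 over 4 such scores). It was 0.76 and 1.07 within the array sets. Plastid-encoded genes lay lower and mitochondrion-encoded genes higher, which a shared carry-over of RNA without poly(A) tails into the labelled pool would move one way. The mean per array of the plastid-encoded genes differed by -0.403 (exact permutation test, two-sided, p = 0.0286), but that of the mitochondrion-encoded genes by 0.399 with p = 0.0571, so carry-over stays open. A p of 0.0286 is the smallest that 4 against 4 arrays can give and takes the arrays as independent samples. Unequal change of green tissue and of dividing tissue, among other explanations, was not tested.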
